A study of Mus musculus with 6 samples.

How the data were processed

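RNA was measured in mProx24 cells, a mouse cell line of the proximal tubule of the kidney, on 6 single-colour Agilent arrays, 1 array for each of 6 conditions. The conditions were control, high glucose, high FFAs (free fatty acids, given as palmitate), hypoxia, triple stimuli (the 3 together) and triple stimuli with rapamycin, an inhibitor of the kinase complex mTORC1. Per the labels, palmitate was given at 150 µM for 9 hours with 0.15% bovine serum albumin, hypoxia was 1% oxygen for 12 hours before it, and rapamycin was given at 0.4 µg/ml for 12 hours before palmitate. The other 3 arrays were at 20% oxygen. The glucose concentrations and the rapamycin vehicle are not given in the sources used here.

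Per the file headers and the submitters' processing notes, the authors scanned the arrays in 1 colour (Cy3) and read them with Agilent Feature Extraction 10.7.3.1, which subtracted background, detrended each array and replaced spots at background by a surrogate. The scanner files hold a linear signal intensity per spot with no scaling between arrays, per the file headers. The deposited value table holds a ratio per probe, the same signal divided by the 75th percentile of its array over all spots, controls included. The scale and the division of that ratio were read from its values. Its median was 0.0505 in the column labelled control, 0.0516 in high glucose, 0.0535 in high FFAs, 0.0562 in hypoxia, 0.0544 in triple stimuli and 0.0561 in triple stimuli with rapamycin.

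The value table was compared with the scanner files array by array. The scanner file labelled high glucose held the values of the table column labelled high FFAs, with an SD of the log2 difference over probes of 4.93e-07, and the scanner file labelled high FFAs held those of the column labelled high glucose, with an SD of 5.02e-07. The other 4 pairs matched under their own labels. The 2 arrays are therefore called array A, labelled high glucose in the scanner file and high FFAs in the value table, and array B, labelled the other way round. Neither was relabelled, and no statement is made in the results on which stimulus each received.

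Analyses started from the scanner files. The log2 processed signal of each spot was reduced by the log2 75th percentile of the non-control spots of its array and averaged over the spots of a probe. Of 55681 probes, 323 carried a non-uniformity or population outlier mark of the scanner software on at least 1 array and were left out, 310 of them probes with several spots. Each gene name was represented by its probe with the highest mean over the 6 arrays, which left 34788 gene names. Of these, 19137 were well above background, by the scanner software's own call, on at least 1 array and 15057 on all 6. Symbols were matched to a RefSeq table, which covered 21924 of the gene names. Probe positions are on mouse genome build mm9 as the files give them, and no exon or untranslated region was annotated, since no genome annotation of that build was used here.

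The comparisons were array A, array B, hypoxia and triple stimuli, each against control, and triple stimuli with rapamycin against triple stimuli alone. A gene entered a comparison when its probe was well above background on at least 1 of the 2 arrays, and was called higher or lower when the log2 difference was at least 1 in size, a 2-fold difference. Where the dimmer array was not well above background, its level was raised to the lowest well-above-background signal of that array, so that the difference is a bound on the dim side. The triple stimuli difference was also set against the sum of the 3 single differences, its genes against the genes that differed with rapamycin, and the 3 arrays at 1% oxygen against the 3 at 20%. With 1 array per condition there was no replicate check, no p-value was computed, and no value has a replicate error. The number of arrays limits the precision of every value.

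Before the data were examined, 20 gene lists and 6 lists of cell type markers were fixed, 576 genes in all, of which 559 were on the arrays after the outlier filter. For each list and comparison the median log2 difference of the measured members was placed among 10000 random lists of the same size matched on expression level. The percentile describes these arrays and is not a p-value. The rule for named genes, the 9 alternatives tried and the counts to be reported were fixed at the same time. Named were, per comparison, the 10 largest and 10 smallest log2 differences among genes well above background on both arrays and at least 2-fold different, with a symbol that is not an accession, clone or predicted model, up to 3 more per direction measured on 1 array only as bounds, and in each list the 4 members with the largest absolute difference. Named besides were the 10 highest and lowest in the oxygen comparison, the 5 furthest above and below the sum of single differences, and the 10 per direction with the largest smaller difference in the rapamycin overlap. Genes named outside this rule were chosen after their values were seen and are introduced so.

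Because several comparisons share an array, a data set with no effects was simulated 100 times on the 15057 genes well above background on all 6 arrays, with noise drawn from the centred differences of array B and control in 10 bins of level, which had an SD per array from 0.077 to 0.25 on the log2 scale and include any effect on array B. Both arrays lay on the first slide row, so this noise leaves out differences between slide rows and any signal added at the first rows of spots. It gave on average 13.0 higher genes and 13.1 lower genes for 1 pair of arrays. The alternatives fixed in advance were quantile normalization, cyclic loess normalization, scaling to the median of probes above background, normexp background correction with an offset of 50, a filter on both arrays, no filter, the median over the probes of a gene, an offset of 32 added before log2, and the deposited value table. A further 3 were added after seeing the data: genes matching the RefSeq table only, dropping marked spots while keeping their probes, and genes whose brighter array was at 4 times its 75th percentile or more, called bright genes in the results. Under each alternative a log2 value was taken as close to the reported one when it moved by less than 0.13, the robust SD of array B minus control.

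The counting rule was tested on simulated data for the comparison of hypoxia with control, on 17198 genes, with 50 genes made higher or lower at each fold. It called 0% of them at 1.5-fold, 80% at 2.5-fold, 100% at 4-fold and 94% at 8-fold, and 28 of 16998 unchanged genes. Genes dim on the control array could not be called in this simulation, and its noise came from array B and control alone. The rate among unchanged genes therefore does not hold for calls on dim genes. In the data, 389 of the 783 genes higher in hypoxia were not well above background on both arrays. The 3 missed genes at 8-fold were made lower and had a control level less than 2-fold above the lowest well-above-background signal of the hypoxia array, so that their bound did not reach 2-fold. For the same reason 3008 of 17283 genes above background on the control array could not be called lower in hypoxia, 3005 in triple stimuli, 1992 on array A and 2509 on array B, and 1202 of 16092 could not be called lower with rapamycin. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and version 1.17.8 of the data.table package for the normalization alternatives.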

Results

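RNA levels in mProx24 proximal tubular cells were measured under control conditions, under 3 single stimuli of the diabetic kidney (high glucose, the fatty acid palmitate, and hypoxia), under the 3 together, and under the 3 together with rapamycin, with 1 array per condition. Of 59305 spots that were not controls, 43.8% were well above background on the control array, 43.1% on array A, 41.2% on array B, 40.9% in hypoxia, 40.3% in triple stimuli and 42.1% in triple stimuli with rapamycin, and 0 were saturated. Array A is the array labelled high glucose in the scanner file and high FFAs in the value table, and array B is labelled the other way round. All 6 arrays lay on 1 slide, the 3 at 20% oxygen on its first row and the 3 at 1% oxygen on its second, so slide row and oxygen cannot be told apart. On the 3 arrays at 1% oxygen, more genes were at least 2-fold different in the first 64 rows of spots than in the last, as 9.53% of genes against 2.03% were higher in hypoxia.

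**Figure D1:**
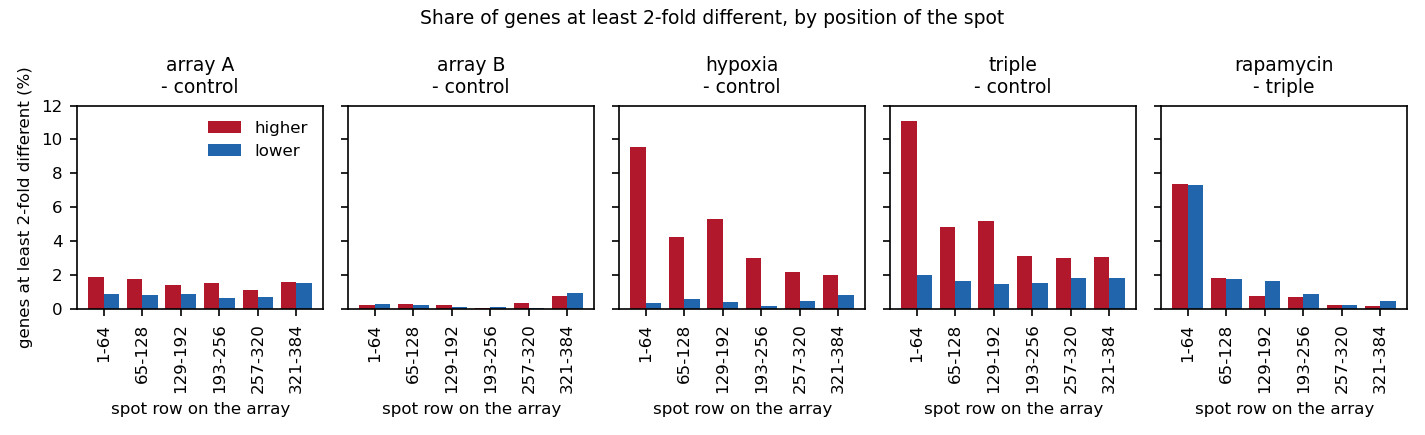
Share of genes (%) at least 2-fold higher (red bars) or lower (blue bars) in each of the 5 comparisons, in 6 bands of 64 rows of spots from the first to the last row of the array. In triple stimuli 11.1% of genes were higher in the first band and 3.06% in the last, while on array A the shares were 1.87% and 1.59%. On array B the last band had the larger shares, 0.77% higher and 0.92% lower against 0.25% and 0.28% in the first.

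Array A was compared with control to see what 1 single stimulus changed, high glucose or palmitate according to which label is taken. Of 33 measured targets of the stress factor ATF4, 14 were at least 2-fold higher, as were 7 of 23 genes of fatty acid oxidation and PPAR targets. Angptl4, which encodes a secreted inhibitor of lipoprotein lipase and is a target of the fatty acid sensor PPAR, had one of the largest differences (log2 difference 3.25; probe on mm9 chromosome 17, 33911880 to 33911939). Atf3 (2.99; chromosome 1, 192994547 to 192994606) and Ddit3 (2.83; chromosome 10, 126732518 to 126732821), a pair of transcription factors induced by stress, were also higher, and Id3, an inhibitor of basic helix-loop-helix factors, was lower (-2.10; chromosome 4, 135700075 to 135700249).

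All 33 measured targets of ATF4, the transcription factor of the integrated stress response, were above 0, with a median log2 difference of 0.95 (percentile 100 among random lists), and 14 were at least 2-fold higher. They included Ppp1r15a at 2.54, which encodes a subunit that directs dephosphorylation of the initiation factor eIF2, and Slc7a11 at 2.48, the cystine importer. Of 23 measured genes of fatty acid oxidation and PPAR targets, 7 were higher and 0 lower, with a median of 0.32 (percentile 99.99). Besides Angptl4 these included the acyl-CoA thioesterases Acot2 at 3.01 and Acot1 at 2.01 and the lipid droplet coat gene Plin2 at 1.85. All 25 measured genes of ribosome biogenesis were above 0 (median 0.53, percentile 100), with Myc at 1.45 and Gnl3 at 0.92, and the immediate early genes had a median of 0.57 (percentile 100), with Klf4 at 1.23, Jun at 1.17 and Nr4a1 at 1.01. Autophagy and lysosome genes had a median of 0.28 (percentile 100; 3 of 34 higher, Sqstm1 at 1.34, Hexa at 1.26 and Neu1 at 1.09), apoptosis and p53 targets 0.25 (percentile 100), with Gadd45a at 1.78 and Plk3 at 1.68, and chaperones of the endoplasmic reticulum (ER) 0.19 (percentile 99.98), with Herpud1 at 1.61 and Dnajb9 at 1.37. The cholesterol synthesis list lay below 0 (median -0.25, percentile 0; 0 of 25 at least 2-fold), with Idi1 at -0.79 and Hmgcs1 at -0.78, as did the cell cycle list (median -0.22, percentile 0; 23 of 28 below 0), with Ccne1 at -0.55 and Cdk1 at -0.44.

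Further genes with the largest differences on array A were Lims2 (2.97), Lce1g (2.72), Tmem179 (2.54) and Dus4l (2.49) on the higher side. On the lower side were Cdkl1 (-2.50), Tgfbi (-2.43), the matrix gene Thbs1 (-1.99), Tafa5 (-1.94), Pcdh18 (-1.70), Cyp1a1 (-1.61), Trabd2b (-1.58), Tmem145 (-1.55) and Il5ra (-1.52). Chst2 was at least 2.61 and Soat2 at least 2.45 on the log2 scale, and Atoh8 was -2.19 or lower. Among bright genes, chosen after their values were seen, Trib3 (2.30) and Hilpda (1.75) were higher and Cbs (-1.27), Id2 (-1.21), Id1 (-1.03) and the water channel Aqp1 (-1.19) lower. Zfp386 had the largest value on array A (4.50), but its probe was low on the control array alone (level -0.98, against 3.49 to 3.73 on the other 5), and its other probes differed by 0.04 and 0.15. In all, 278 genes were higher and 160 lower of 17806 measured. Of genes well above background on both arrays 205 were higher and 95 lower, and of bright genes 86 and 13 of 7105. Among bright genes the medians of fatty acid oxidation, autophagy and lysosome, and HIF targets outside glycolysis were 0.15, 0.43 and 0.52, the last against 0.28 over all measured members. Of these 26 HIF targets 20 were above 0 and 5 at least 2-fold higher (percentile 100), although array A was at 20% oxygen. Angptl4 is in this list and in that of fatty acid oxidation and PPAR targets. HIF targets in glycolysis had a median of 0.12 (percentile 99.2), with 2 of 20 at least 2-fold higher.

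Array B was compared with control to see what the other single stimulus changed. Txnip, a glucose-responsive gene that encodes an inhibitor of thioredoxin and of glucose uptake, was 2.97-fold higher (log2 difference 1.57; probe on chromosome 3, 96365147 to 96365206), and its other probe gave 1.73. It led the list of glucose-responsive targets of the factors MondoA and ChREBP, whose 8 measured members had a median of 0.28 (percentile 100), with Arrdc4 at 0.82 and Gpd1 at 0.46 and 1 member at least 2-fold higher. The cholesterol synthesis list had a median of -0.26 (percentile 0), with 23 of 25 members below 0 and 0 at least 2-fold, among them Idi1 at -0.42 and Nsdhl at -0.40.

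The fatty acid synthesis list also lay below 0 on array B (median -0.17, percentile 0), with Lpin1 at -0.52, Gpam at -0.43 and the desaturases Scd2 at -0.32 and Scd1 at -0.31. ATF4 targets had a median of -0.06 (percentile 0), with Trib3 at -0.55 and Cth at -0.52, NRF2 targets 0.07 (percentile 98.1), with Nqo1 at 0.51, and fatty acid oxidation and PPAR targets 0.06 (percentile 90.5), with Angptl4 at 0.61. In all, 55 genes were higher and 50 lower of 17496, and 19 and 13 of those well above background on both arrays. Other higher genes were Tent5b (2.21), Cep44 (1.63), Gli3, Dus4l, Grik2 (1.10), Frat1 (1.06), Npw (1.05) and Etnk2 (1.01), besides Zfp386 (4.50), of which Zfp386, Tent5b, Gli3 and Dus4l were higher than control on all 5 other arrays. Lower genes were Lockd (-3.64), Cmtm4 (-1.57), Trav3n-3 (-1.38), Il4i1 (-1.06) and Ap2b1 (-1.01). The Lockd probe was low on array B alone (level 0.16, against 3.46 to 4.37 on the other arrays), and the other probe of Cmtm4 gave 0.02. Of bright genes 5 were higher, Zfp386, Tent5b, Txnip, Gli3 and a probe without a gene symbol, and 3 lower, Lockd, Ap2b1 and another such probe, chosen after their values were seen.

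Hypoxia was compared with control, the comparison of 1% with 20% oxygen without the other stimuli. Most targets of hypoxia-inducible factor (HIF) in the fixed lists were at least 2-fold higher. Ak4, a mitochondrial adenylate kinase, was 24.1-fold higher (log2 difference 4.59; probe on chromosome 4, 101139464 to 101139523), Bnip3, which encodes a receptor for removal of mitochondria, reached 3.14 (chromosome 7, 146082760 to 146082819; other probes 3.11 and 3.62), and Egln3, which encodes a HIF prolyl hydroxylase, was at least 20.7-fold higher (at least 4.37; chromosome 12, 55280953 to 55281012). Of 27 measured HIF targets outside glycolysis 20 were at least 2-fold higher, with a median of 1.59 (percentile 100), and of 20 in glycolysis 13 were, with a median of 1.32 (percentile 100).

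The glycolytic HIF targets included the pyruvate dehydrogenase kinase gene Pdk1 (2.86), Aldoc (2.86), the lactate exporter gene Slc16a3 (2.48) and Pfkp (2.21), and the others Ankrd37 (3.92) and the ER oxidase gene Ero1a (2.65; chromosome 14, 45904192 to 45904251). Mgarp (4.42; chromosome 3, 51192355 to 51192414), which encodes a mitochondrial protein, and Pygl (4.17; chromosome 12, 71291855 to 71291914), the liver-type glycogen phosphorylase, stood outside the lists. Ribosome biogenesis genes were below 0 in 24 of 25 cases (median -0.33, percentile 0), with Dkc1 at -0.72 and Rrp9 at -0.69. Apoptosis and p53 targets had a median of -0.32 (percentile 0), with Plk3 at -1.01 and Btg2 at -0.97 against Bcl2l11 at 1.04, and NRF2 targets -0.19 (percentile 0.32), where Gsta2, a glutathione transferase gene, was at -1.34 and the metallothionein genes Mt2 and Mt1 at 1.26 and 1.22. ATF4 targets had a median of 0.15 (percentile 100; 5 of 32 higher), with Vldlr at 2.24, Ddit3 at 2.02 and Aldh1l2 at 1.75. The heat shock list had a median of -0.17 (percentile 2.27), and cytosolic ribosomal protein genes 0.08, which turned to -0.13 with quantile normalization.

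Among the other largest values in hypoxia were Selenbp1 (3.32; chromosome 3, 94748621 to 94748680), Acap1 (3.32), Pik3r5 (3.27), Hsd17b2 (3.24) and Slc25a21 (3.19) and, as bounds, Il12rb2 (4.52) and Caps2 (4.21). The spots of Ak4, Bnip3, Acap1, Pik3r5, Slc25a21, Il12rb2 and Caps2 lay in the first 64 rows, as did those of Irx3 and Gsta2 among lower genes. Genes lower in hypoxia included the immediate early gene Egr1 (-1.96; chromosome 18, 35024395 to 35024454), Txnip (-1.65), Med17 (-2.01), Sprr2g (-1.73), Irx3 (-1.43), Klhdc8b (-1.31) and Rasl11b (-1.30) and, as bounds, Iffo1 (-1.70), Acot1 (-1.63) and the claudin gene Cldn2 (-1.48; chromosome X, 136345244 to 136345303). Zfp386 gave 4.68 with the probe that was low in control. Psmd9 gave -2.62 with a probe that was low on this array alone, and -0.19 with its other probe. In bright genes, chosen after their values were seen, Ndrg1 (2.31), Ddit4 (2.29), Bhlhe40 (2.24) and Krt42 (2.17) were higher. In all, 783 genes were higher and 83 lower of 17791 measured. Of bright genes 179 were higher and 12 lower of 7056, and in the last 2 of the 6 bands of spot rows 122 were higher and 36 lower of 5759. The last band alone held 23 of these 36 lower genes, of which 7 were well above background on both arrays.

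Triple stimuli were compared with control, the question being what the 3 stimuli did together. HIF targets outside glycolysis had a median of 1.64 (20 of 26 at least 2-fold higher, percentile 100) and those in glycolysis 1.04 (10 of 20, percentile 100), with Ak4 at 4.32 (spot in the first 64 rows), Egln3 at 4.25 or more, and Pfkp at 2.30. All 32 measured ATF4 targets were above 0, with a median of 1.14 and 20 at least 2-fold higher (percentile 100), led by Atf3, 12.6-fold higher (3.66), and Ddit3 (2.95). Immediate early genes of the growth factor response had a median of 1.51 (13 of 16 higher, percentile 100), with Junb at 2.51, Jun at 2.06, Myc at 2.05 and Ier3 at 1.92.

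Genes of inflammation under NF-kB had a median of 0.38 in triple stimuli (percentile 99.96; 6 of 18 higher and 1 lower). Cxcl2 (2.48; chromosome 5, 91334534 to 91334593) and Cxcl1 (1.44), which encode neutrophil chemoattractants, and Ptgs2 (2.19), the inducible cyclooxygenase, were higher, and Cxcl5 was lower (-1.30). The median of this list was 0.51 over bright genes. Ribosome biogenesis genes had a median of 0.40 (percentile 100), apoptosis and p53 targets 0.16 (percentile 98.5), with Gadd45a at 2.08 and Pmaip1 at 1.75, and the fibrosis list 0.22 (percentile 99.5), with Ccn1 at 1.02 and Thbs1 at -1.78. All 25 measured genes of cholesterol synthesis were below 0 (median -0.48, percentile 0), with Idi1 at -1.40 (chromosome 13, 8891524 to 8891583) and Dhcr7 at -1.07. The interferon list had a median of -0.42 (percentile 0.1), with Ifit3 at -2.01 (chromosome 19, 34663105 to 34663164), Xaf1 at -1.09 and Isg15 at -0.99, but -0.053 over bright genes. Oxidative phosphorylation genes had a median of -0.23 (percentile 0.21; 24 of 27 below 0), with Ndufa4 at -0.63. The lists of fatty acid oxidation (-0.01, percentile 51.8), ER chaperones (0.00, percentile 68.8), NRF2 targets (-0.10, percentile 17.9) and glucose-responsive genes (-0.05, percentile 42.1) held members far from 0, among them Acot2 (2.85), Pdk4 (2.08), Herpud1 (1.71), Hmox1 (2.42) and Txnip (2.55). Over bright genes the medians of the fibrosis, ER chaperone and glucose-responsive lists were 0.075, -0.17 and 1.42.

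Further genes with large differences in triple stimuli were Mgarp (3.81), Pygl (3.53), Lims2 (3.30), Ankrd37 (3.29), Ero1a (7.98-fold), Nabp1 (3.33; spot in the first 64 rows) and Areg (3.21; chromosome 5, 91570090 to 91570149), which encodes a ligand of the EGF receptor. Bright genes, chosen after their values were seen, included Hilpda (2.95), Angptl4 (2.92), Ppp1r15a (2.89), Krt19 (2.75) and Trib3 (2.72). On the lower side were Sprr2g (-2.76; chromosome 3, 92179092 to 92179151), Ifit3b (-2.31), Hsd3b4 (-2.26), Cyp1a1 (-2.25), Dhrs3 (-2.18), Aldh4a1 (-1.99), Cys1 (-1.92) and Nod1 (-1.90) and, as bounds, Klhl14 (-3.16), Cdkl1 (-2.59) and Atoh8 (-2.07). Sort1 gave -1.91 with 1 probe and 0.22 with its other, and Zfp386 gave 4.47 with the probe that was low in control. In all, 903 genes were higher and 303 lower of 17789 measured, 221 and 58 of 7176 bright genes, and 175 and 105 of 5770 in the last 2 bands of spot rows. Among genes measured on all 6 arrays 413 were higher and 219 lower, against at most 20 and 22 in simulation without effects, whose noise leaves out slide row and spot position.

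**Figure D2:**
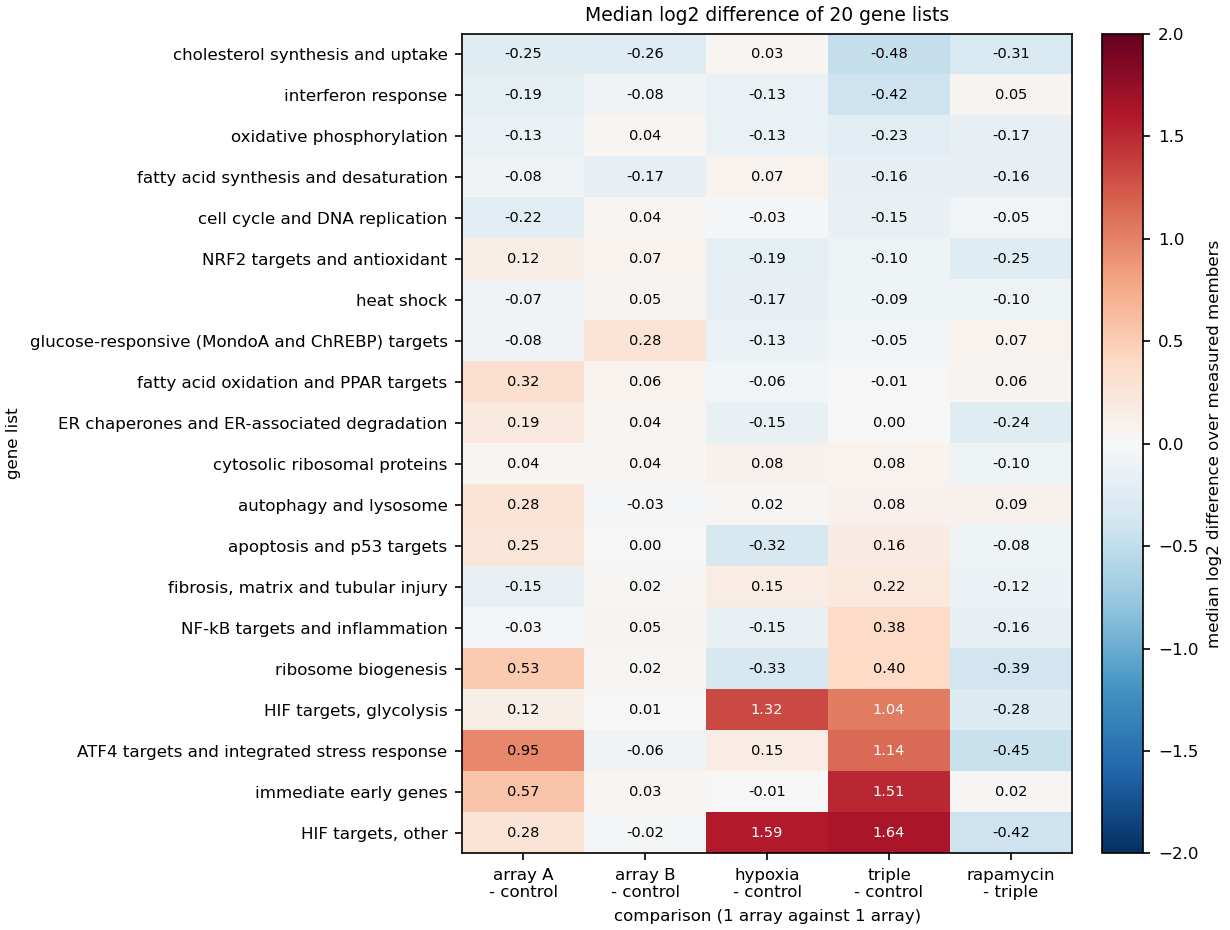
Median log2 difference of the measured members of 20 gene lists (rows) in the 5 comparisons (columns), each of 1 array against 1 array, with red above 0 and blue below 0. HIF targets were at 1.32 and 1.59 in hypoxia, ATF4 targets at 0.95 on array A and 1.14 in triple stimuli, and ribosomal proteins, at 0.08 in hypoxia and triple stimuli, changed sign with quantile normalization.

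Triple stimuli were set beside the single stimuli to ask whether the combination equalled their sum. Of genes measured on all 6 arrays, 125 of the 178 higher on array A, 150 of the 324 higher in hypoxia and 8 of the 12 higher on array B were also among the 413 higher in triple stimuli. Of lower genes, 30 of 68 on array A, 11 of 43 in hypoxia and 0 of 11 on array B were among the 219 lower in triple stimuli. The control array enters all of these differences, and no overlap without effects was simulated for them. Of the 413 higher genes 167, and of the 219 lower genes 180, were not 2-fold different in the same direction under any single stimulus. Genes just under 2-fold on a single array are among those counted by this rule, so these counts alone do not set the combination apart from the sum. Egr1 lay furthest above the sum of the 3 single differences (3.49), as it was at -1.96 in hypoxia and 1.35 in triple stimuli, followed by Lockd (2.99), Txnip (2.85), Lhx9 (2.54) and Cmtm4 (2.46). Lockd and Cmtm4 were lower on array B than in control, which lowers their sum. The Lockd probe was low on array B alone, and the other probe of Cmtm4 did not repeat the difference on array B. Furthest below the sum were Zfp386 (-9.21), Tent5b (-3.96), Pik3r5 (-3.34), Gli3 (-3.06) and Dus4l (-2.84), where 4 of these 5 were higher than control on all 5 other arrays, and the control level enters the sum 3 times and the triple stimuli difference once. In all, 143 genes lay at least 2-fold above and 211 below the sum of 15132. Without any effect, simulation gave on average 142 genes above the sum (113 to 175) and 161 below (126 to 193), against 139 and 198 on the same 15057 genes.

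Correlations across genes, which are not independent replicates, between differences that share the control array are raised by it, and simulation without effects gave 0.50 (0.44 to 0.56). The correlation with triple stimuli was 0.70 for array A, 0.55 for hypoxia, inside the simulated range, and 0.18 for array B. The covariance was 0.116 for array A, 0.0993 for hypoxia and 0.0159 for array B, against 0.0179 (0.0152 to 0.0216) in the simulation. In pairs that share no array, array A minus array B and triple stimuli minus hypoxia gave 0.57, and hypoxia minus array B and triple stimuli minus array A gave 0.50. In the second of these pairs, both differences set an array of the second slide row against an array of the first. A difference between slide rows would raise that correlation too, so it cannot be assigned to oxygen.

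Rapamycin was tested by comparing triple stimuli with and without it. Several of the fixed lists had medians below 0 with rapamycin, with most members less than 2-fold different. ATF4 targets had a median log2 difference of -0.45 (percentile 0; 31 of 33 below 0), with Aldh1l2 at -1.01, Cth at -0.92 and Psph at -0.89. HIF targets outside glycolysis had a median of -0.42 (percentile 0; 23 of 27 below 0), with Ero1a at -1.11, Car12 at -1.07 and the transferrin receptor gene Tfrc at -1.02, and those in glycolysis -0.28 (percentile 0; 19 of 20 below 0), with Pfkfb3 at -0.78 and the glucose transporter gene Slc2a1 at -0.66. Ribosome biogenesis genes had a median of -0.39 (percentile 0; 24 of 25 below 0), with Rrp9 at -0.66 and Ppan at -0.57.

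Cholesterol synthesis genes, already lower in triple stimuli, had a further median of -0.31 with rapamycin (percentile 0; 23 of 25 below 0), with Lss at -0.66 and Sqle at -0.58. ER chaperones had a median of -0.24 (percentile 0.01), with Hyou1 at -0.73 and Hspa5 at -0.61, and NRF2 targets -0.25 (percentile 0.06), with Gsta2 at -1.08. In the NF-kB list (median -0.16, percentile 1.03) Cxcl2 was 4.37-fold lower (-2.13) and Cxcl1 was at -1.16, while Ccl5 was at 0.79. Autophagy and lysosome genes had a median of 0.09 (percentile 99.97), with Wipi1 at 0.46, Atg14 at 0.44 and Ulk1 at 0.42 against Sqstm1 at -0.49, and 0 of 34 were at least 2-fold different. Fatty acid oxidation and PPAR targets had a median of 0.06 (percentile 93.2), with Acot1 at 1.19 and Cpt1a at 0.62. Cytosolic ribosomal protein genes had a median of -0.10, which turned to 0.034 with quantile and 0.037 with cyclic loess normalization, and oxidative phosphorylation genes -0.17, which moved to -0.035 with quantile normalization. The median of all genes was -0.04. The triple stimuli array enters this difference and that from control with opposite sign, and across genes the correlation of the 2 differences was -0.36, against -0.50 in simulation without effects, and the covariance -0.0475 against -0.0180.

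Among the largest single values with rapamycin were higher ones for Ciita (2.67), Apcdd1 (2.53), Slc11a1 (2.40), Sohlh2 (2.33), Il4ra (2.31), Ncald (2.16), Ptger4 (1.86), Frat2 (1.65; other probe 0.03) and Slc40a1 (1.64), and lower ones for Lhx9 (-2.49), Cd38 (-2.44), Il12rb1 (-2.20), Olfr1052 (-1.84), Aifm3 (-1.71), Cdsn (-1.71; chromosome 17, 35693799 to 35693858), Ldb3 (-1.71), Olfr1311 (-1.65) and Hsd17b2 (-1.60). Of the 10 largest 8, and of the 10 smallest 6, had their spot in the first 64 rows. Bounds were 4.34 for Rnft2 and 4.25 for Ror1. Bright genes, chosen after their values were seen, included Selenbp1 (-1.40), Slc14a1 (-1.11), Hmox1 (-0.96), Krt19 (-0.92), Neat1 (0.67) and Pink1 (0.65). In all, 335 genes were higher and 370 lower of 17244 measured, but 1 and 8 of 7033 bright genes, and 10 and 19 of 5416 in the last 2 bands of spot rows. The bright higher gene was Mettl27 (1.05), whose other probe gave -1.19.

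**Figure D3:**
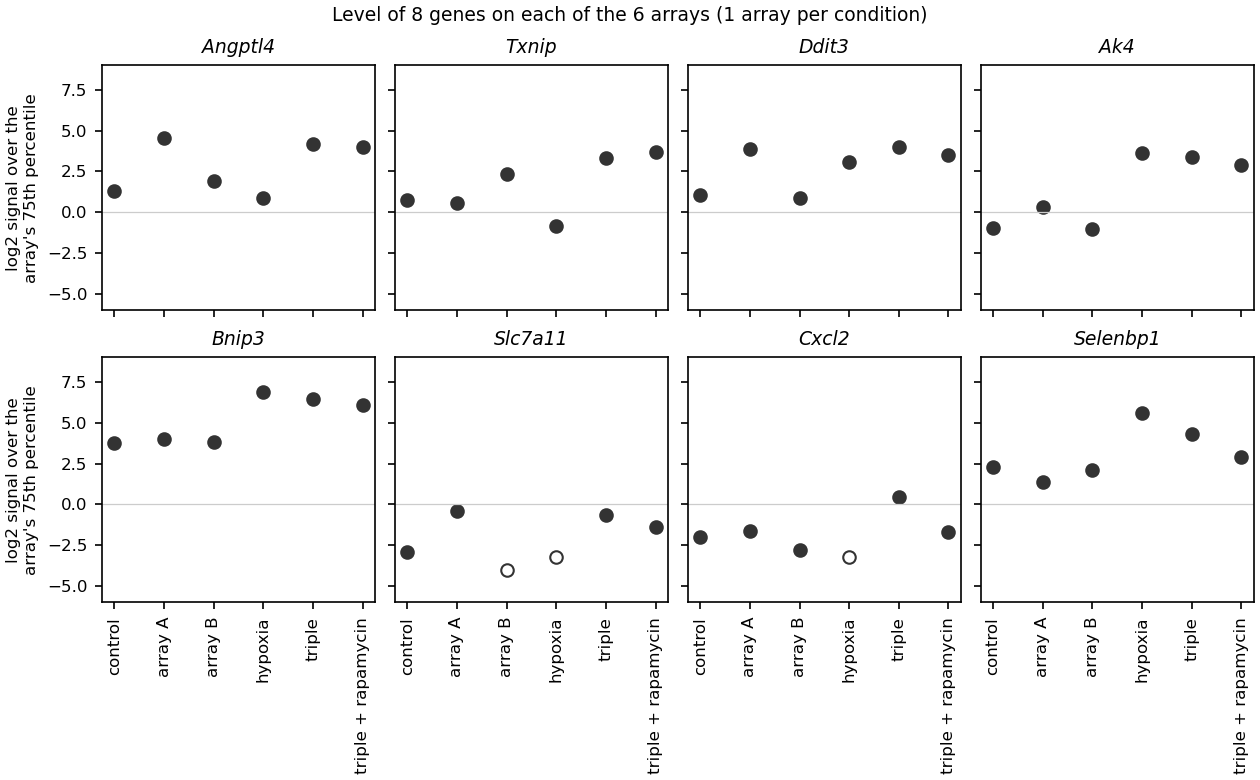
Level of 8 genes on each of the 6 arrays, as log2 signal over the array's 75th percentile, with 1 point per array and open points where the probe was not well above background. Angptl4 was at 4.53 on array A and 4.20 in triple stimuli against 1.29 in control, and Ak4 at 3.64 in hypoxia and 3.36 in triple stimuli against -0.95 in control.

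Genes higher in triple stimuli and lower with rapamycin, and the reverse, were counted to see which differences were smaller with rapamycin. Of 16678 genes, 330 were at least 2-fold higher in triple stimuli and at least 2-fold lower with rapamycin, and 8 were the other way. The named genes of the first kind, Rtl3 (-3.58 with rapamycin), Serpina10 (-3.45), Myo7b (-3.39), Mylpf (-3.34), Pth2 (-3.29), Slc6a3 (-3.27), Cntfr (-3.15), Nlrp4a (-3.05), Dnm3 (-3.02) and Ppp1r3e (-2.98), were all bounds, and 9 of these 10 had their spot in the first 64 rows. Those of the other kind were Ncald (2.16), Sv2a (1.72), Vwa5a (1.56), the interferon-induced gene Ifit3b (1.29), Bmf (1.20), Kazald1 (1.17) and Iffo1 (1.07), with bounds for Sv2a, Vwa5a and Kazald1. Of the 330 genes, 261 lay in the first 2 bands of spot rows and 11 in the last 2, and 6 were bright. The triple stimuli array enters both differences with opposite sign, and on the 15057 genes measured on all arrays 35 genes of the first kind stood against 6.55 (2 to 13) in simulation without effects, and 4 of the other kind against 3.66 (0 to 9). That noise came from a pair of arrays of the first slide row and leaves out the signal at the first rows of spots of the second, while 12 to 34 of the 15057 genes were at least 2-fold above the other 5 arrays on 1 array at 1% oxygen alone, against 0 to 5 on 1 array at 20%.

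The 3 arrays at 1% oxygen were set against the 3 at 20% to find genes that separated the 2 groups of arrays. Only control and hypoxia differed in oxygen alone, since no array at 20% received the other 2 stimuli together or rapamycin. Slide row also went with oxygen, so these genes cannot be assigned to oxygen alone. In 38 genes the lowest level at 1% oxygen was at least 2-fold above the highest at 20%, and in 1 gene, Cldn2, which encodes a claudin of leaky tight junctions, the order was reversed (-1.05). The gaps were largest for Pygl (3.38), Mgarp (3.28), Egln3 (3.06), Tmem74b (2.99), Ankrd37 (2.67), Ak4 (2.53), Bnip3 (2.04), Pdk1 (1.82), Gsc2 (1.79) and Bend5 (1.78). The spots of Ak4, Bnip3 and Gsc2 lay in the first 64 rows and those of Pdk1 and Bend5 in the next 64. The spot of Cldn2 lay in row 323, in the last 64. The gaps of Pygl, Egln3, Tmem74b, Gsc2 and Cldn2 are bounds, and among bright genes the counts were 22 and 0. Over the alternatives the count of higher genes ran from 22 to 72 and that of lower genes from 0 to 18.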

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

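The alternatives that use only RefSeq-matched genes, bright genes, or marked spots dropped with probes kept were chosen after seeing the data, and the other 9 before. No paired analysis was possible because each condition has 1 array and no shared replicate pairs. Between 40.3% and 43.8% of spots were well above background, and the counts of genes changed with how dim genes were treated. A value was counted as reversed only if its sign changed and the reported value was over 0.13 in size for a list or at least 1 for a gene. Other changes of sign were counted as moved or close by their size, so the reversed values are not all the changes of sign. Of the values for gene lists under all alternatives, 1287 stayed close to the value reported, 45 moved and 2 reversed. Of the values for named genes 5874 stayed, 482 moved and 1 reversed, and of the counts 102 stayed within 1.5 times and 90 did not. No scaling alternative moved the median of all genes by over 0.1. With marked spots dropped and probes kept, every count stayed within 1.5 times. The settings that change the filter or the level required differ by construction in which genes enter. For quantile, cyclic loess, median scaling, normexp, the median over probes and the offset the cause was not tested.

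With quantile normalization, 136 genes were lower in hypoxia (83 as reported), 4 lower in every 1% oxygen array (1 as reported) and 14 lower in triple stimuli and higher with rapamycin (8 as reported). The median of cytosolic ribosomal proteins was -0.13 in hypoxia and -0.084 in triple stimuli (0.08 in both as reported) and 0.034 with rapamycin (-0.10), and that of oxidative phosphorylation with rapamycin was -0.035 (-0.17). Cyclic loess gave 0.037 for ribosomal proteins with rapamycin and 2 genes lower in every 1% oxygen array, and scaling to the median of probes above background gave 0 such genes.

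With normexp correction, counts of higher and lower genes were 141 and 36 on array A (278 and 160 as reported), 12 and 6 on array B (55 and 50), 477 and 19 in hypoxia (783 and 83), 499 and 114 in triple stimuli (903 and 303), and 148 and 159 with rapamycin (335 and 370). It gave 0 genes lower in every 1% oxygen array, 45 above and 46 below the sum of single differences (143 and 211), and 152 and 0 genes that were higher then lower, or lower then higher, with rapamycin (330 and 8). Immediate early genes on array A had a median of 0.43 (0.57), and the interferon list in triple stimuli -0.22 (-0.42). With an offset of 32, counts were 174 and 61 on array A, 15 and 11 on array B, 30 lower in hypoxia, 170 lower in triple stimuli, 218 and 234 with rapamycin, 0 lower in every 1% oxygen array, 73 above and 94 below the sum, and 215 and 0 in the rapamycin overlap.

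With genes well above background on both arrays, 95 were lower on array A, 19 higher and 13 lower on array B, 394 and 45 in hypoxia, 485 higher in triple stimuli, 58 and 88 with rapamycin, 0 lower in every 1% oxygen array, and 48 and 5 in the rapamycin overlap. In triple stimuli the medians were 1.49 for HIF targets outside glycolysis (1.64), -0.58 for interferon and 0.22 for glucose-responsive genes (-0.05).

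With no filter, counts were 1713 and 1112 on array A, 1323 and 890 on array B, 2349 and 855 in hypoxia, 2489 and 1206 in triple stimuli, 1316 and 1451 with rapamycin, 72 and 18 in the oxygen comparison (38 and 1), 2767 above and 4256 below the sum, and 979 and 250 in the rapamycin overlap. Proximal tubule markers reversed on array A, to 0.12 (-0.22), and fibroblast markers in triple stimuli, to -0.18 (0.25). On array A the medians were -0.031 for interferon (-0.19) and 0.15 for glucose-responsive genes (-0.08). In triple stimuli they were 1.49 for HIF targets outside glycolysis, 0.23 for fatty acid oxidation (-0.01), 0.57 for NF-kB (0.38), 0.040 for fibrosis (0.22) and 0.47 for glucose-responsive genes, and with rapamycin -0.20 for interferon (0.05).

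With the median over the probes of a gene, Lrp2 reversed in triple stimuli, to 0.060 (-1.10), NF-kB targets in triple stimuli had a median of 0.51, 0 genes were lower in every 1% oxygen array and 216 were in the rapamycin overlap. Under the labels of the value table, high glucose gave 54 and 53 genes and palmitate 270 and 164, which is the label conflict, since under the scanner labels they gave 278 and 160, and 55 and 50.

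With RefSeq-matched genes, counts were 31 and 17 on array B, 417 higher in hypoxia, 582 higher in triple stimuli, 180 and 207 with rapamycin, 131 below the sum and 182 in the rapamycin overlap. With bright genes they were 86 and 13 on array A, 5 and 3 on array B, 179 and 12 in hypoxia, 221 and 58 in triple stimuli, 1 and 8 with rapamycin, 22 and 0 in the oxygen comparison, 20 above and 16 below the sum, and 6 and 0 in the rapamycin overlap. The medians of bright genes on array A were 0.52 for HIF targets outside glycolysis (0.28), 0.15 for fatty acid oxidation (0.32), -0.26 for fatty acid synthesis (-0.08), 0.43 for autophagy (0.28) and -0.30 for NF-kB (-0.03). In hypoxia they were 1.93 for HIF targets outside glycolysis (1.59), -0.29 for ER chaperones (-0.15) and 0.062 for interferon (-0.13). In triple stimuli they were 1.97 for HIF targets outside glycolysis, -0.17 for ER chaperones (0.00), 0.51 for NF-kB, -0.053 for interferon, 0.075 for fibrosis, 1.42 for glucose-responsive genes and 1.66 for immediate early genes (1.51). The share of higher genes among all called shifted with the setting too, on array A from 63.5% to 79.7% with normexp, 74.0% with the offset and 86.9% in bright genes, on array B from 52.4% to 66.7% with normexp, 64.6% with RefSeq-matched genes and 62.5% in bright genes, in hypoxia from 90.4% to 73.3% with no filter, and with rapamycin from 47.5% to 11.1% in bright genes.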

Other observations

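The tests on the label conflict, on the spot positions of dim probes, on the array shared by triple stimuli and rapamycin differences, and on other splits of the arrays were chosen only after the result was seen, and the genes named in the next 2 paragraphs were chosen after their values were seen unless they belong to a fixed list.

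Markers of the proximal tubule were only partly present in these cells, as 8 of 26 were well above background in control, against 1 of 12 for the thick ascending limb, distal tubule and collecting duct, 1 of 7 for podocytes, 2 of 9 for fibroblasts, 2 of 8 for endothelium and 5 of 9 for macrophages and leukocytes. The bicarbonate transporter gene Slc4a4 was higher in hypoxia (2.18; probe on mm9 chromosome 5, 89663838 to 89663897) and in triple stimuli (1.77), and the proximal tubule list had a median of 0.33 in hypoxia (percentile 99.7), 0.19 on array B (percentile 99.93), -0.22 on array A (percentile 4.99, reversed to 0.12 with no filter) and 0.03 in triple stimuli (percentile 63.8). Over the alternatives the median of this list ran from -0.66 to 0.60 in triple stimuli and from -0.60 to 0.12 on array A. The endocytic receptor gene Lrp2 was at -1.10 in triple stimuli, but at 0.060 with the median over its probes, and Aqp1 at -0.93. Flt1, an endothelial marker that is also a HIF target, was higher in hypoxia (2.25) and triple stimuli (2.08), while Kdr was at 0.23 and 0.00. The macrophage list had a median of 0.31 in hypoxia (percentile 99.5), with Csf1r at 0.70, 0.04 in triple stimuli and -0.28 with rapamycin (percentile 1.19), and the lysosomal marker Cd68 was at 1.92 on array A, 1.39 in triple stimuli and -0.78 with rapamycin. The distal list had a median of 0.34 on array A over 3 measured genes, the fibroblast list 0.25 in triple stimuli over 3 (reversed to -0.18 with no filter), and the podocyte gene Synpo was at -0.08 on array A. The tubular injury markers Havcr1 and Lcn2 were at -0.02 and 0.29 in triple stimuli.

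Several genes went apart under array A and hypoxia. Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, was at 1.19 on array A, -1.17 or lower in hypoxia and 0.35 in triple stimuli, Acot1 at 2.01, -1.63 or lower and -0.13. Selenbp1 was at -0.91 on array A and 3.32 in hypoxia. Slc7a11 was at 2.48 on array A and 2.21 in triple stimuli but at -0.20 or lower in hypoxia, and Id3 at -2.10, -1.61 and 0.11. Vegfa, which encodes the main endothelial growth factor, was at 1.10 on array A, 1.93 in hypoxia and 1.95 in triple stimuli, and Mt2 at 1.49, 1.26 and 1.36. Genes left out because their probe carried an outlier mark included the cytokine gene Csf2, at 3.13 or more on array A and 5.15 or more in triple stimuli, the HIF target Fam162a, at 2.19 in hypoxia and 2.16 in triple stimuli, and Fos, at 1.85 or more in triple stimuli.

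The scanner file labelled high glucose and the value-table column labelled high FFAs are 1 array, and the reverse holds for the other, so at least 1 set of labels is wrong for this pair. If the value-table columns were the exchanged ones, array A would be high glucose and the glucose-responsive list would be expected to lie higher on it. The median of this list in array A minus array B was -0.32 (percentile 0.36 among random lists), which argues weakly against that reading. Its 8 measured members went both ways, 5 below 0 and 3 above. If the scanner files were exchanged, array A would be palmitate, and the fatty acid oxidation and PPAR list did lie higher on it (median of array A minus array B 0.27, percentile 99.97). A candidate explanation is therefore that the scanner files of the 2 arrays were exchanged, but it rests on what each stimulus is assumed to do to a list and on 1 array each. A response of these cells to glucose or palmitate that departs from both lists stays open, and nothing in the files decides it.

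Many dim probes with a single spot were well above background on 1 array alone and at least 2-fold above all other arrays there. They numbered 307 in hypoxia, 265 in triple stimuli and 299 with rapamycin, against 16 in control, 6 on array A and 6 on array B. Expression of those genes is argued against by where the spots lay, as 69.7% of the 871 probes were in the first 64 rows of spots, which hold 16.6% of probes, and 0 were in the last 2 of the 6 bands. A test written beforehand on other probes of the same genes gave 1.56% of 1471 bright on the same array alone, against 1.02% of all probes, but its positive control gave 0% of 18, so it could not have shown expression, and the judgement was moved to position after this was seen. Signal added at the first rows of these 3 arrays may account for these dim genes, whose highest level was 1.40 on the log2 scale over the 75th percentile. What added it stays open, and since these 3 arrays are all those on the second slide row and all those at 1% oxygen, slide position and oxygen cannot be separated.

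Genes at least 2-fold higher in hypoxia were lower with rapamycin, with a median log2 difference of -0.29 over 351 genes, of which 290 were below 0, against -0.04 over all genes. These genes were picked without the triple stimuli array, which argues against its shared noise as the whole cause. A difference that depends on intensity and signal added at the first rows are argued against too, since random genes matched on level had a median of -0.065 (-0.09 to -0.04), and the 103 genes in the last 2 bands of spot rows had -0.31, against -0.03 over all genes there. A reduced response to hypoxia under rapamycin may be part of this, as a hypothesis found and tested on the same arrays. It would also raise genes that hypoxia had lowered in triple stimuli. The 43 genes lower in hypoxia had a median of -0.10, with 18 higher with rapamycin. Only 11 of these 43 were also at least 2-fold lower in triple stimuli, so they cannot decide whether the response was reduced. A difference between these 2 cultures other than the drug stays open, as there is 1 array each. The 200 genes higher on array A also had a median of -0.27, which does not tell the drug from such a difference.

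In the oxygen comparison the real split of the arrays gave 39 genes, and the highest of the other splits, control, array B and hypoxia against array A and both triple stimuli arrays, gave 61. That split is itself a contrast of treatment, since triple stimuli include both glucose and palmitate and so the stimulus of array A under either set of labels. These were the 2 splits of 10 with as many genes as oxygen gave, and each of the other 8 gave 0 or 1. The splits of 6 arrays are too few for a share under 0.05.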
